A study of Drosophila melanogaster with 18 samples.

How the data were processed

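RNA-seq of whole Drosophila melanogaster was deposited for wild type and a CRISPR knock-out of CG7804 in embryos, L3 larvae and pupae. Per the labels, flies were kept at 25 °C, and embryos were collected for 4 h after a pre-collection of 1 h and aged for 4 h. The authors deposited raw read counts per gene from HTSeq after Trim Galore and TopHat, with no versions given, in 18 files of 17471 genes and 5 categories of reads given to no gene. The genome build, the annotation and the strand setting used in counting are not given in the sources used here. Names and positions were taken by FlyBase identifier from the Ensembl annotation of the BDGP6 assembly, which named 17242 of the genes and left 229 without a symbol. Reads with more than 1 alignment were not counted, so members of close gene families have fewer reads than their RNA.

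Titles gave a number to each sample and marked repeats. Repeats were taken as repeat runs of 1 numbered sample and their counts were summed, which gave 12 samples, 2 in each of 6 groups. The third run of wild-type embryo 2, with 65547365 of its 68533374 reads, carries another library name in its file name, and whether it was a separate library or collection is not given in the sources used here. Differences between kinds of library within wild-type embryo 2 and all values of rRNA-poor wild-type embryos rest on that run. Where both runs were of the same kind of library, the spread between repeats was 1.07 to 1.33 times that of Poisson counting (chi-square over its degrees of freedom), and where the kinds differed it was 298 to 683 times. Depth was 4749991 to 68533374 reads in genes per sample, and a floor of 3 reads over a group was used for genes with no reads in it. Intervals and floors cover counting error only. For ratios with 1 to 3 reads in a group, the exact conditional (Clopper-Pearson) 95% interval is given. Runs in which genes named as rRNA took over 5% of the reads in genes were called rRNA-rich.

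Counts were fitted with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter by group, which left 13334 genes, and a quasi-likelihood fit with 1 term per group and 6 residual degrees of freedom. The common biological coefficient of variation was 0.247. Knock-out was compared with wild type within each stage and on average over the stages, and a joint test asked whether the effect differed between stages. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, except those given as unadjusted and the permutation p of neighbouring genes. Tests were 2-sided, except those of overlap between stages and of neighbouring genes, which asked for an excess only. Before the data were examined, 41 gene lists were written from textbook knowledge, of which 39 had 3 or more tested genes. They were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01. They were also tested with the correlation estimated per list and with fry. With an estimated correlation, camera called 0 lists in embryos, larvae, pupae and on average (3, 4, 2 and 0 at an unadjusted p under 0.05), against 14, 14, 7 and 6 with the preset correlation and 5, 1, 1 and 0 by fry. Medians, means and tests of the called lists shared their sign.

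The fits, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, per stage, the 10 genes with the largest changes in each direction among those called, with a mean log2 CPM of at least 1 and with samples of the genotypes that did not overlap. For the average it took 6 genes in each direction with the same sign at all 3 stages. For the difference between stages it took 6 genes, those with the smallest p. CG7804 and TBPH were always named. Other genes are examples from the lists, those with the smallest p, and w, y, CG3552, CG3434, CR32745 and the genes named as shared between stages were chosen after their values were seen.

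The pipeline was tested on simulated counts with the groups, depths and spread of the data, in 5 draws with 100 genes changed per size. Genes were drawn independently of each other and without kinds of library. The rates below therefore do not cover errors from the kind of library or from correlation between genes, on which the list tests depend. The number of draws was raised from 1 to 5 after the false calls of the first draw were seen. A log2 change of 2 was recovered for 84.6%, 82.8% and 83.8% of genes in embryos, larvae and pupae, and a change of 1 for 12.4%, 8.6% and 10%. For the average these shares were 99.2% and 82%, and for the difference between stages 35.6% and 0.8%. False calls were 4.57%, 6.89% and 8.61% of the calls at the 3 stages, 4.40% for the average and 11.7% for the difference between stages. Those of larvae, pupae and the difference between stages exceeded the nominal 5%. A planted list of 30 genes raised by 1 was called by camera at each stage, and had adjusted p = 0.077, 0.064 and 0.27 with an estimated correlation.

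Alternatives were DESeq2-type and upper-quartile scaling, no filter or a stricter one, DESeq2 1.42.0, limma voom, each run as its own replicate, the deepest run, runs of 1 flow cell, only the samples of a stage, the runs of wild-type embryo 2 taken apart, a replicate block by sample number, a 2-fold minimum, and each sample left out in turn. After the kinds of library were seen, the kind as a covariate (13362 genes), the removal of rRNA genes, each kind alone and a crossed replicate block were added. With the covariate, runs were summed for each sample and kind. Wild-type larvae 1 and wild-type embryo 2, which had both kinds, thus entered as 2 columns each, counted as separate replicates. The p-values and counts of that fit take these columns as independent, and its common biological coefficient of variation was 0.210. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The 5 categories of reads given to no gene were left out of all fits.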

Results

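RNA of whole wild-type animals and of animals with a CRISPR knock-out of CG7804 was sequenced at 3 stages: embryos, L3 larvae and pupae of mixed age. The design of the series is this comparison of genotypes, and its title concerns a young gene and its interactions with essential genes. Each of the 6 groups held 2 numbered samples, 12 in all, and 18 sequencing runs were deposited as read counts for 17471 genes. Reads in genes came to 6368194 and 68533374 in the wild-type embryo samples, 13688062 and 63822362 in knock-out embryos, 67119333 and 11625114 in wild-type larvae, 5396686 and 11643876 in knock-out larvae, 4749991 and 6716380 in wild-type pupae, and 26777944 and 9904093 in knock-out pupae. Levels are CPM, read counts relative to the TMM-scaled library size, as mean ± SD with n = 2, and changes are log2 fold changes of knock-out over wild type with the standard error (SE) and the adjusted p of edgeR. The labels do not say that numbered samples were separate cultures or collections, so every p measures only the spread between these samples.

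Transcripts of CG7804 itself were still read in knock-out larvae. CG7804 (FBgn0036496, now also named cocoon, chromosome 3L, 15472197 to 15474110, protein coding) had 19.1 and 21.1 CPM in wild-type larvae and 0.904 and 8.05 CPM in knock-out larvae, from 4 and 82 reads. The log2 fold change was -2.03 (SE 0.72, adjusted p = 0.17), which did not pass the test. In pupae the 2 wild-type samples had 5.11 and 19.9 CPM and the knock-out samples 6.47 and 4.69 CPM (-1.20, SE 0.70, adjusted p = 0.45). In embryos 4 reads were found in wild type (0 and 0.0543 CPM) and 1 in knock-out (0.0626 and 0 CPM). CG7804 was thus hardly read in wild-type embryos, even with 68533374 reads in genes in wild-type embryo 2. A loss there could not be detected. In embryo samples 3 reads were 0.0407 to 0.454 CPM. TBPH, the parent gene of CG7804 and the fly homolog of TDP-43, differed by 0.26, -0.37 and 0.11 in embryos, larvae and pupae (SE 0.23 at each stage, adjusted p = 0.46, 0.44 and 0.86). The larval change of CG7804 was -4.48 (adjusted p = 0.041) without knock-out larvae 2 and -1.32 (adjusted p = 0.39) without knock-out larvae 1. It was -2.34 (adjusted p = 0.036) with the kind of library as a covariate. In that fit the 2 kinds of library of wild-type larvae 1 counted as separate replicates. The labels do not say which bases the knock-out removed.

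**Figure D1:**
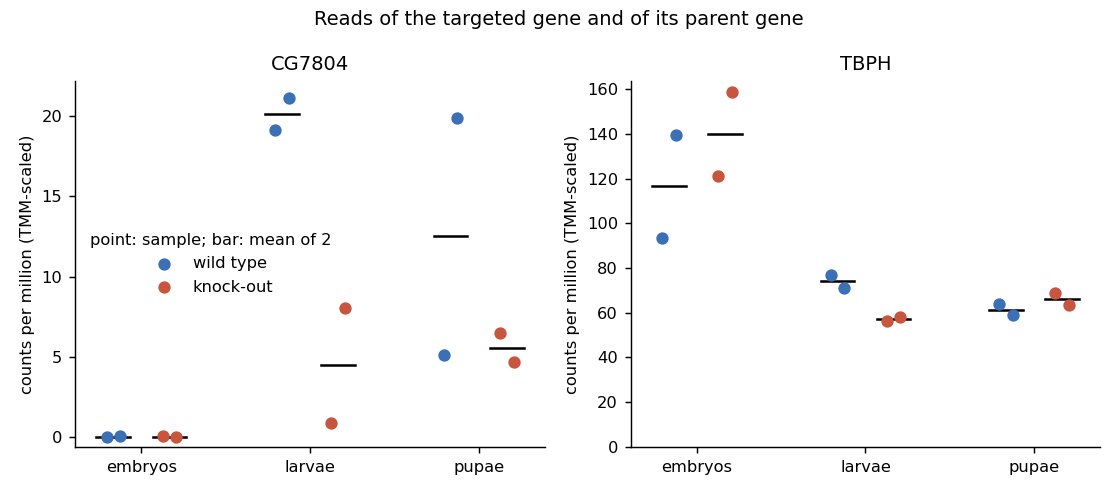
CPM of CG7804 and TBPH in each of the 12 numbered samples, by stage and genotype (each point is 1 sample, lines are means of 2). CG7804 lay at 19.1 and 21.1 CPM in wild-type larvae and at 0.904 and 8.05 CPM in knock-out larvae.

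The libraries were of 2 kinds, which did not follow the groups evenly. In 9 runs ribosomal RNA genes took 12.4% to 36.2% of the reads in genes, and in the other 9 they took 0.121% to 0.577%. All knock-out embryo and knock-out pupal runs were rRNA-poor and both wild-type pupal samples were rRNA-rich. Wild-type embryo 1 and 2 of the 3 runs of wild-type embryo 2 were rRNA-rich. Larvae had both kinds in both genotypes. Within 1 numbered sample, the rRNA-poor library of wild-type larvae 1 exceeded the rRNA-rich one by a median log2 difference of 0.51 over 88 oxidative phosphorylation genes and of 0.73 over 81 cytoplasmic ribosomal protein genes. In wild-type embryo 2 these differences were 0.61 and 0.72, with the third run as the rRNA-poor library. That run held 65547365 of the 68533374 reads of the sample, and the labels do not say whether it was a separate library or collection.

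**Figure D2:**
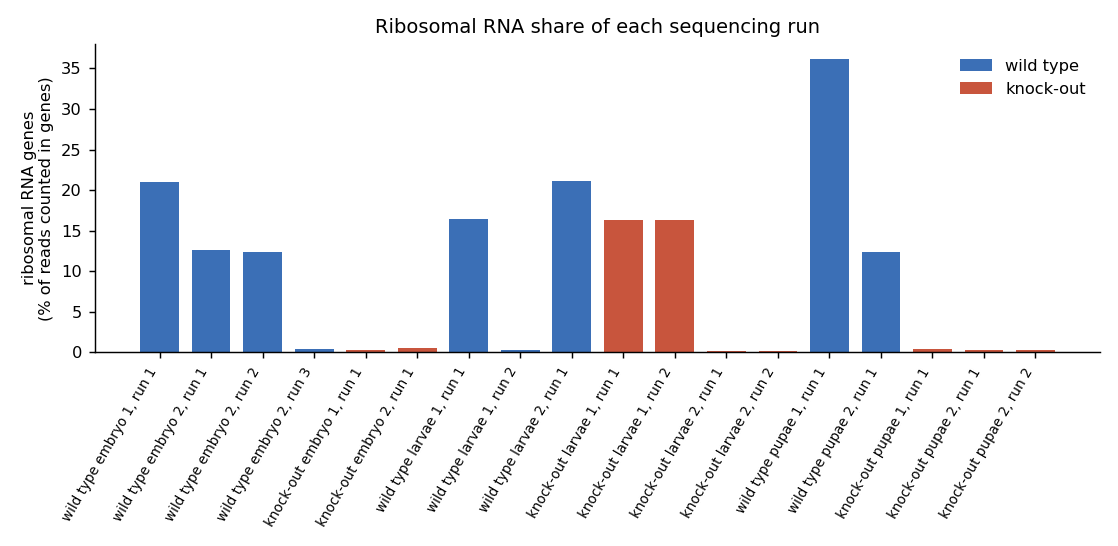
Percent of the reads in genes that fell on ribosomal RNA genes, for each of the 18 runs, by stage and genotype. The 9 rRNA-rich runs lie between 12.4% and 36.2% and the 9 rRNA-poor runs between 0.121% and 0.577%.

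In knock-out embryos, 14 of 27 neuron and synapse genes fell and 13 did not pass the test, and all 27 had negative changes with a median of -1.24. Syt1, which encodes the calcium sensor of synaptic vesicles, fell from 102 ± 3.9 to 38.0 ± 4.79 CPM (-1.43, SE 0.21, adjusted p = 0.00757). Snap25, a SNARE protein of the synapse, fell from 11.0 ± 5.27 to 2.87 ± 0.16 CPM (-1.87, SE 0.35, adjusted p = 0.0183). Syn and nrv3, for synapsin and a neuronal sodium pump subunit, fell by 1.55 and 2.03 on the log2 scale (adjusted p = 0.0196 and 0.018). Adjusted over the list alone, 22 of the 27 fell. Camera gave the list an adjusted p = 6.1e-12, and adjusted p = 0.52 with an estimated correlation. In rRNA-poor libraries alone, which hold the third run of wild-type embryo 2 and both knock-out embryo samples, the median was -1.25.

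All 30 tested genes of DNA replication and the cell cycle had positive changes in knock-out embryos, with a median of 0.79. The test over all genes called 5 of them (24 adjusted over the list alone): CycB, the mitotic cyclin B, rose from 1022 ± 164 to 2126 ± 126 CPM (1.06, SE 0.23, adjusted p = 0.0239), and the replication licensing genes dup and Mcm2 rose by 1.12 and 0.90. The list had an adjusted p = 9.5e-12 by camera and adjusted p = 0.51 with an estimated correlation. Of 22 ovary and maternal transcripts, 3 rose (9 adjusted over the list alone), among them alphaTub67C, a maternal tubulin, from 21.5 ± 5.19 to 58.2 ± 19.7 CPM, and smg, the maternal RNA regulator smaug, from 584 ± 121 to 1190 ± 126 CPM. Their median was 0.90 (adjusted p = 1.8e-07, and adjusted p = 0.51 with an estimated correlation). The 24 segmentation genes all had positive changes (median 0.61). Of these edgeR called 0, with 6 at an unadjusted p under 0.05, and DESeq2 and voom called 6 and 3. The 24 neurogenesis genes had a median of 0.51 with 1 call (0 adjusted over the list alone), E(spl)m8-HLH, a Notch target, at 0.97. These 2 lists had camera adjusted p = 0.00024 and 0.00048, each with adjusted p = 0.65 with an estimated correlation. Of 81 cytoplasmic ribosomal protein genes only RpS10a rose (2.77), and the list median was 0.33 (adjusted p = 0.0014, and adjusted p = 0.82 with an estimated correlation), or 0.15 with the kind of library as a covariate.

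Among 28 muscle structure genes 1 fell in knock-out embryos (12 adjusted over the list alone): Mf, for the thick filament protein myofilin, from 401 ± 130 to 152 ± 2.51 CPM (-1.40, SE 0.33, adjusted p = 0.0328). Of 110 cuticle genes 4 fell (3 adjusted over the list alone), all of the Cpr family, such as Cpr49Ag at -1.43 and Cpr49Ae at -1.93. Of 22 genes of chitin synthesis and turnover 4 fell (8 adjusted over the list alone), among them knk, needed for chitin organisation, at -1.53 and the chitinase gene Cht10 at -1.30. With the kind of library as a covariate Mf and Cht10 had adjusted p = 0.064 and 0.053. Of 23 genes of the ecdysone response 6 fell: ImpE2 from 277.2 ± 47 to 89.5 ± 25.9 CPM, and Eip74EF, br and Eip63F-1 at -1.27, -1.67 and -1.38. Adjusted over the list alone, 9 fell and 1 rose. The medians of these 4 lists were -0.92, -0.76, -0.86 and -0.77 (camera adjusted p = 3.7e-05, 3.7e-05, 0.00085 and 0.0014), each with adjusted p = 0.65 with an estimated correlation. Of 63 detoxification genes 10 fell and 1 rose (15 and 3 adjusted over the list alone), with the cytochrome P450 gene Cyp6a20 from 21.4 ± 8.85 to 2.38 ± 0.789 CPM (median of the list -0.59, adjusted p = 0.025, and adjusted p = 0.69 with an estimated correlation). The detoxification call was lost with DESeq2-type size factors, without wild-type embryo 1, without knock-out embryo 2 and with rRNA-poor libraries alone (adjusted p = 0.051, 0.050, 0.10 and 0.073).

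Among single genes in embryos, CG30416 and CG33655 had no reads in wild-type embryos and were at least 83.8-fold and at least 44.3-fold higher in knock-out embryos, with the floor at 3 reads over the group. CG9861, which lies next to CG30416 on 2R, rose from 0 and 0.0679 CPM to 7.20 and 11.6 CPM. Cp15, a chorion protein gene of the eggshell, rose from 0.151 and 0.136 CPM to 20.4 and 6.62 CPM (6.55, adjusted p = 0.0031). CG10013 and CG5781 rose by 4.05 and 4.64, and lncRNA:CR32657 by 4.53. CG15734 was higher by a ratio of 13.6 (95% counting interval 3.41 to 118, from 2 and 26 reads). I-3 and CG8065 were at least 10.1-fold and at least 3.84-fold higher. In the other direction, mthl8, a receptor gene of the methuselah family, had 506 reads in wild type and 0 in knock-out and was at least 161-fold lower. Drsl5, a drosomycin-like peptide gene, fell from 62.5 and 61.5 CPM to 0 and 0.0659 CPM. CG42831 was lower by a ratio of 345 (95% counting interval 95.2 to 2856) and CG32305 by 208 (57.3 to 1724), from 2 knock-out reads each. CG32301 fell by 6.19 on the log2 scale. CG5062, CG42876, CG34188, CG15109 and CG4714 had no knock-out reads and were at least 44.9-, 24.2-, 17.5-, 8.27- and 6.68-fold lower.

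The test over 13334 genes called 874 genes in embryos, 178 higher and 696 lower. CG7804 itself was hardly read in wild-type embryos (0 and 0.0543 CPM), and whether these calls reflect its loss was not tested. DESeq2-type size factors called 2132 genes, 42.9% of them higher, and upper-quartile scaling, which moved the median of all genes by -0.16, called 2012. Without wild-type embryo 2 the split turned, with 1121 genes higher and 575 lower (66.1% higher), and without the third run of that sample 67.1% of 3391 were higher. The count was 1552 with the kind of library as a covariate, 345 without wild-type embryo 1, 26 without knock-out embryo 1, 399 without knock-out embryo 2, 471 and 472 without wild-type larvae 1 or 2, and 579 and 227 without knock-out pupae 1 or 2. Of the 20 genes with the largest changes, 8 were no longer called without knock-out embryo 1, 6 without knock-out embryo 2, and 4 and 5 without wild-type embryos 1 or 2.

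In knock-out larvae, 7 of 12 larval cuticle genes rose (9 adjusted over the list alone), with a median of 2.14. Lcp9 rose from 47.0 ± 18.9 to 236 ± 15.8 CPM (2.34, SE 0.30, adjusted p = 0.003), and Lcp65Ag2 and Lcp65Ag1, close copies of each other, rose by 2.69 and 3.10. Of all 110 cuticle genes 20 rose (27 rose and 2 fell adjusted over the list alone), with a median of 0.50. The adjusted p by camera was 4.8e-12 for larval cuticle and 6.2e-08 for all cuticle, and adjusted p = 0.22 and 0.51 with an estimated correlation. Of 28 muscle structure genes 2 rose (17 adjusted over the list alone): the troponin C gene TpnC47D from 33.9 ± 14.5 to 118 ± 11 CPM and the actin gene Act87E from 134 ± 39.2 to 339 ± 90.2 CPM. The muscle median was 1.03 (adjusted p = 2.7e-09, and adjusted p = 0.51 with an estimated correlation).

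Of 63 detoxification genes 11 rose in knock-out larvae (17 adjusted over the list alone), with Cyp6a2, a cytochrome P450 gene tied to insecticide metabolism, from 1.15 ± 0.944 to 54.3 ± 35.6 CPM (5.34, SE 0.60, adjusted p = 0.002) and the glutathione transferase genes GstE8 and GstE5 at 2.03 and 1.56. Of 48 digestive enzyme genes 6 rose (8 adjusted over the list alone), among them the trypsin gene thetaTry from 181 ± 11.7 to 676 ± 227 CPM and Npc2d, for a sterol-binding protein, at 3.85. Of 20 genes of lipid and sugar storage 3 rose (8 adjusted over the list alone): the fatty acid synthase genes FASN2 and FASN1 at 2.66 and 1.55, and Glyp, for glycogen phosphorylase, at 1.59. Of 11 salivary glue genes 3 rose (4 adjusted over the list alone), with Sgs1 from 499 ± 250 to 1783 ± 79.5 CPM. The medians of these 4 lists were 0.40, 0.78, 0.55 and 0.59 (camera adjusted p = 6.2e-08, 3.7e-07, 1.3e-06 and 0.00042). They had adjusted p = 0.48, 0.72, 0.51 and 0.51 with an estimated correlation. Larval serum and fat body proteins had 1 call of 6, Fbp2 at 1.96, and juvenile hormone genes 2 of 11, the epoxide hydrolase genes Jheh1 and Jheh3 (2 and 2 adjusted over the list alone; list adjusted p = 0.010 and 0.021, and adjusted p = 0.51 and 0.47 with an estimated correlation). Neither of these lists was called without knock-out larvae 2 (adjusted p = 0.070 and 0.051), and the second was not called in rRNA-rich libraries alone (adjusted p = 0.12).

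Of 26 testis genes 25 had negative changes in knock-out larvae (median -0.75) and 1 fell (1 adjusted over the list alone), ProtB, a protamine of sperm chromatin, from 19.3 ± 1.18 to 7.10 ± 3.01 CPM. Of 14 heat shock genes 13 had negative changes (median -0.95) and DnaJ-1, an Hsp40 chaperone gene, fell from 156 ± 44.7 to 66.8 ± 17.1 CPM (1 and 5 calls over all genes and adjusted over the list alone). Camera gave adjusted p = 4.3e-05 for testis genes and 0.00013 for heat shock genes, and adjusted p = 0.72 and 0.22 with an estimated correlation. The testis call was lost without knock-out larvae 1 and in rRNA-poor libraries alone (adjusted p = 0.12 and 0.068).

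Among single genes in larvae, CG17105 rose from 6.10 and 2.32 CPM to 138 and 111 CPM (4.80, adjusted p = 0.00099). CG32071, Cpr65Aw, Cpr67Fa1, trp, Alp7, CG32073 and CG14258 rose by 5.75, 4.35, 4.11, 3.89, 3.77, 3.61 and 3.60 on the log2 scale. Of these, trp encodes the light-activated channel of photoreceptors and Alp7 an alkaline phosphatase. The gene mthl8 again had no knock-out reads and was at least 52.6-fold lower, and Nepl8, for a neprilysin-like protein, was at least 2.31-fold lower. From 1 knock-out read each, lncRNA:CR43166 was lower by a ratio of 249 (95% counting interval 44.6 to 9836) and CG17177 by 71.0 (12.7 to 2810). CG11893, CG4783, CR32745, CG43120, stl and CG43235 fell, with log2 fold changes of -4.69, -4.61, -4.55, -4.13, -4.01 and -3.98.

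The test called 435 genes in larvae, 351 higher and 84 lower. Fitted on the 4 larval samples alone, edgeR called 0 genes, with 2048 at an unadjusted p under 0.05, while DESeq2 and limma voom on all samples called 1164 and 703. Without knock-out larvae 2 it called 155 higher and 183 lower genes (45.9% higher). The count was 53 without wild-type larvae 1, 76 without wild-type larvae 2, 180 without knock-out pupae 2 and, without knock-out pupae 1, 242 higher and 35 lower genes. Of the 20 genes with the largest changes, 4 and 3 were no longer called without wild-type larvae 1 or 2, and 1 and 2 without knock-out larvae 1 or 2. The count was 1232 with the kind of library as a covariate.

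In knock-out pupae, 13 of 37 tested immunity genes rose and 24 did not pass the test, with a median of 1.95, and 22 rose adjusted over the list alone. The drosocin gene Dro rose from 19.2 ± 13.2 to 677 ± 320 CPM (5.19), AttD, an attacin gene, from 3.88 ± 0.59 to 126 ± 15 CPM (5.05, adjusted p = 0.00022), and the cecropin gene CecB from 28.1 ± 1.69 to 336 ± 53.2 CPM (3.58). BomBc1, a bomanin gene, and the drosomycin-like gene Drsl3 rose by 6.67 and 4.82. AttA, AttB and AttC, attacin genes of which AttA and AttB are near-identical copies, rose by 5.32, 5.31 and 5.02. Camera gave the list an adjusted p = 7.2e-28, and adjusted p = 0.37 with an estimated correlation. Outside the list, edin, a peptide gene induced by infection, rose from 3.47 ± 0.351 to 839 ± 28.3 CPM (7.89, SE 0.93, adjusted p = 0.0019), and PGRP-SC1b, a peptidoglycan amidase gene, was higher by a ratio of 66.0 (95% counting interval 22.5 to 321, from 3 and 729 reads). Wild-type pupae were all rRNA-rich and knock-out pupae all rRNA-poor. With the kind of library as a covariate 12 of the 37 genes rose and the median was 1.99.

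**Figure D3:**
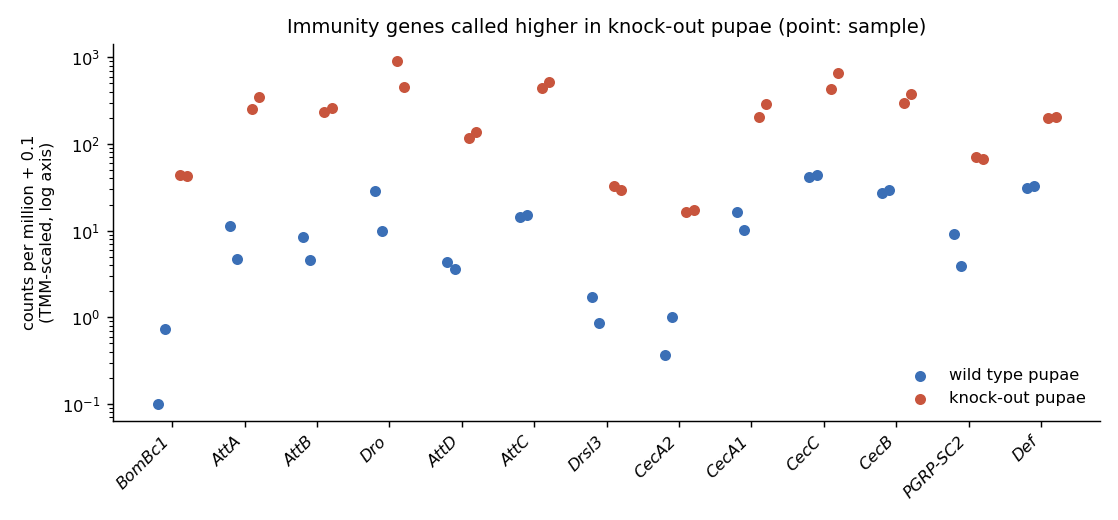
CPM plus 0.1 (log axis) of the 13 genes of the immunity list that rose in knock-out pupae, for each wild-type and knock-out pupal sample. AttD lies at 4.30 and 3.47 CPM in wild type and at 116 and 137 CPM in knock-out pupae.

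Of 12 larval cuticle genes 2 fell in knock-out pupae (3 adjusted over the list alone): Lcp65Ad from 376 ± 206 to 11.5 ± 0.0577 CPM (-5.03, SE 0.53, adjusted p = 0.0011) and Lcp65Ag2 from 136 ± 83.9 to 20.2 ± 4.3 CPM (-2.75). The list median was -0.97 (adjusted p = 5.8e-05, and adjusted p = 0.66 with an estimated correlation). Of 14 heat shock genes 1 rose (7 adjusted over the list alone), the small heat shock gene Hsp26 from 266 ± 23.1 to 923 ± 66 CPM, and the median was 0.70 (adjusted p = 2.4e-05, and adjusted p = 0.25 with an estimated correlation). Of 27 neuron and synapse genes 1 fell (7 adjusted over the list alone), cac, a calcium channel gene of the synapse, from 85.8 ± 28.9 to 25.0 ± 1.63 CPM. Of 88 oxidative phosphorylation, 81 ribosomal protein and 30 DNA replication genes edgeR called 0, over all genes or adjusted over the list alone, with 21, 17 and 4 at an unadjusted p under 0.05. DESeq2 called 2, 2 and 1 of them and voom 0. The medians of the neuron list and these 3 lists were -0.51, 0.57, 0.42 and 0.33 (camera adjusted p = 2.4e-05, 2.0e-06, 0.0002 and 0.0029), each with adjusted p = 0.99 with an estimated correlation. With the kind of library as a covariate, the neuron, oxidative phosphorylation and ribosomal protein lists had medians of -0.26, -0.17 and -0.19 and were no longer called (adjusted p = 0.45, 0.95 and 0.71), and the DNA replication list had a median of 0.17. In the same fit Hsp26 and cac were not called (adjusted p = 0.17 and 0.15). The larval cuticle and DNA replication calls were lost without wild-type pupae 1 (adjusted p = 0.086 and 0.23) and the ribosomal protein call without wild-type pupae 2 (adjusted p = 0.073).

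Among other single genes in pupae, CG43920 rose by 5.14 on the log2 scale. CG15617 fell from 250 and 208 CPM to 0.361 and 0.418 CPM (-9.21, adjusted p = 8.2e-05). The gene mthl8, lncRNA:CR43166 and CG34251 had no knock-out reads and were at least 171-, 50.3- and 23.3-fold lower. CG43133, CG17177, Miox and CG14327 fell, with changes of -5.60, -5.33, -4.90 and -4.65, where Miox encodes myo-inositol oxygenase. CG8960 was lower by a ratio of 36.8 (95% counting interval 5.24 to 1598, from 10 and 1 reads), and its adjusted p was 0.059 with the kind of library as a covariate.

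The test called 174 genes in pupae, 58 higher and 116 lower. In this stage genotype and kind of library were fully confounded, and the covariate took its value from the embryo and larval samples; with it 140 genes were called, 94 of them among the 174. The count was 17 without knock-out pupae 1, 27 without knock-out pupae 2, 113 and 115 without knock-out embryos 1 or 2, and 12 with the runs of 1 flow cell, where 1 knock-out sample remained. Of the 20 genes with the largest changes, 12 were no longer called without knock-out pupae 1, 7 without knock-out pupae 2, and 3 and 6 without wild-type pupae 1 or 2, while edin, Dro and AttD were called without each sample in turn.

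**Figure D4:**
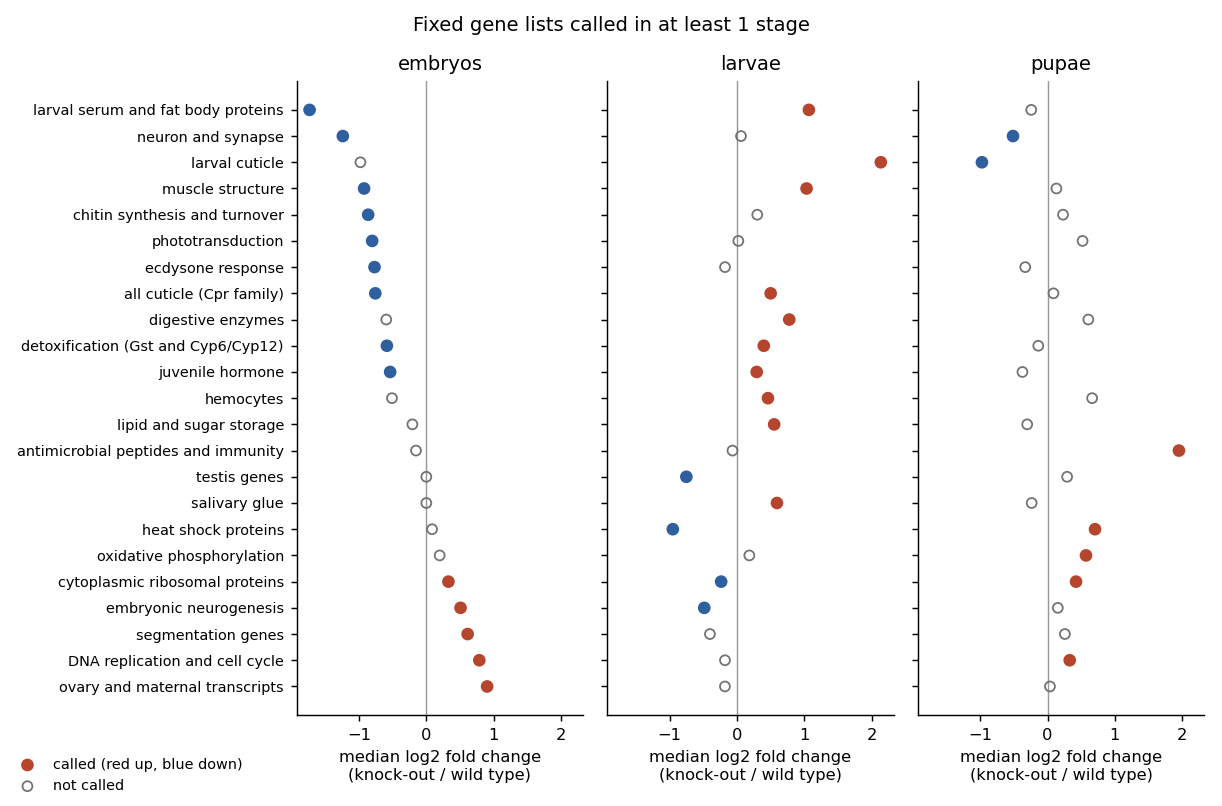
Median log2 fold change of knock-out over wild type for 23 gene lists in embryos, larvae and pupae (each point is 1 list, red where camera called it higher and blue where lower). Neuron and synapse genes lie at -1.24 in embryos and immunity genes at 1.95 in pupae, and no called list changed direction with DESeq2-type or upper-quartile scaling.

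A few genes changed at every stage. CG3552 and CG3434 were called higher at all 3 stages, and w, mthl8 and CR32745 lower. In embryos, larvae and pupae mthl8 had 506, 843 and 139 wild-type reads and 0 knock-out reads at each stage. Differences between the stocks could also give changes at every stage. Whether the changes of these genes come from such differences or from the loss of CG7804 was not tested. The white gene w, an eye pigment transporter on the X chromosome (2790599 to 2796466), fell from 1.15 ± 0.124 to 0.0659 ± 0.0932 CPM in embryos, from 8.09 ± 1.2 to 0.456 ± 0.326 CPM in larvae, and from 12.3 ± 1.46 to 2.19 ± 0.92 CPM in pupae. The body colour gene y rose in larvae (2.61, adjusted p = 0.021) and pupae (1.47, adjusted p = 0.043, and adjusted p = 0.21 with the kind of library as a covariate). Genes lower in both embryos and pupae numbered 30 against 6.05 under independence (exact hypergeometric test, p = 8.2e-13 adjusted over 6 overlaps), and included Cyp6a20, Cyp6a8 and Cyp6g1. Larvae and pupae shared 11 higher genes against 1.53 and 11 lower genes against 0.731 (adjusted p = 4.1e-07 and 4.4e-10). All stages shared 1 estimate of the spread of each gene, which can place the same genes among the calls of several stages. All knock-out embryo and pupal runs were also rRNA-poor, while wild type was rRNA-rich in part or in full. Independence is thus not the level to expect without a shared effect of the genotype, and these p-values do not measure one. CG3552 and CG3434 lie side by side on 3L, and the strand used in counting is not given.

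On average over the stages, CG16995 rose by 3.08 (SE 0.40, adjusted p = 0.0028) and was called in larvae (3.59) and pupae (2.76). Cyp6a2 rose by 2.97 (SE 0.33, adjusted p = 0.0012), with 1.98, 5.34 and 1.57 in embryos, larvae and pupae. The immunity genes edin, AttA and BomBc1 rose by 3.60, 3.38 and 3.17 on average, with their largest changes in pupae. In embryos, larvae and pupae edin had 2.58, 0.32 and 7.89, AttA 3.65, 1.17 and 5.32, and BomBc1 1.02, 1.83 and 6.67. CG42876 fell from 182 ± 10.5 to 19.3 ± 1.2 CPM in pupae and had 1.503 ± 0.33 CPM in wild-type and 0.437 ± 0.34 CPM in knock-out larvae (adjusted p = 0.16). Among the genes named here, mthl8, lncRNA:CR43422, Ir67b, CG33258 and RabX2 fell and lncRNA:CR45228 rose, each with a group at 0 reads, so that no average fold is given. Of the 12 genes named for the average, 3 were called without each sample in turn. Of these 12, lncRNA:CR43422 and CG33258 were not called with the kind of library as a covariate (adjusted p = 0.058 and 0.098). Of the 10 tested strain marker genes, w fell and y rose, and the list was not called (adjusted p = 0.14).

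The test of the average called 536 genes, 142 higher and 394 lower, and 288 with the kind of library as a covariate, 231 of them shared. Without wild-type embryo 2 it called 348 higher and 333 lower genes, and without the third run of that sample 822 higher and 649 lower. The count was 304 without wild-type embryo 1, 129 and 321 without knock-out embryos 1 or 2, 212 and 155 without wild-type larvae 1 or 2, 313 without knock-out larvae 2, 293 without wild-type pupae 1, and 72 and 81 without knock-out pupae 1 or 2.

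The change of knock-out over wild type differed between stages for 610 genes. In simulated counts 11.7% of the calls of this test were false. The kind of library followed the genotype in full in pupae and in part in embryos, while larvae had both kinds in both genotypes. An effect of the kind alone could therefore differ between stages, and this test cannot tell it from an effect of the genotype. CHKov1, a choline kinase-like gene, had changes of -4.46 (SE 0.30) in embryos, -0.36 (SE 0.24) in larvae and -0.51 (SE 0.25) in pupae (adjusted p of the difference 0.0013). Npc2d had -1.03, 3.85 and -3.54, and Abca3, an ABC transporter gene, -1.41, 1.35 and -1.40 in the same order (adjusted p = 0.0015 and 0.0013). CG15044 had -1.04, 0.61 and -3.0, and CG9861 7.17, -0.64 and -0.14. CG30416 was read in knock-out embryos alone at that stage but had -1.92 in larvae (adjusted p = 0.033) and -1.51 in pupae. The count was 151 and 354 without knock-out embryos 1 or 2, 120 and 197 without wild-type larvae 1 or 2, and 275 and 166 without knock-out pupae 1 or 2. It was 1752 with the kind of library as a covariate.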

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

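Of the tests below, those of library kind, of unfertilised eggs, of a single knock-out sample, of reads from TBPH and of wild-type RNA in the knock-out larval and pupal samples were chosen after the result was seen; the test of younger embryos was written before its result was seen.

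The change of knock-out over wild type differed between stages for 610 genes in the joint test. The kinds of library were spread unevenly over genotypes and stages. This test and those of the lists below therefore cannot tell an effect of the genotype from one of the kind. Of 39 gene lists, the change differed for 20 between embryos and larvae, 14 between embryos and pupae and 16 between larvae and pupae when the difference itself was tested with camera (adjusted over the 39 lists for each pair of stages). Each of these lost its call with an estimated correlation. For 9 of the lists the difference lay between 2 stages at which the list was called in opposite directions. Muscle structure genes had a difference of medians, larvae minus embryos, of 1.96 (adjusted p = 1.4e-11, and adjusted p = 0.36 with an estimated correlation). For larval serum and fat body proteins it was 2.80, for all cuticle genes 1.26 and for detoxification genes 0.984 (adjusted p = 0.0012, 1.1e-07 and 1.1e-07, and 0.36, 0.37 and 0.36 with an estimated correlation). It was 0.830 for juvenile hormone genes, -0.992 for neurogenesis genes and -0.562 for cytoplasmic ribosomal protein genes (adjusted p = 0.0015, 2.5e-05 and 2.5e-05, and 0.35, 0.36 and 0.69 with an estimated correlation). Between pupae and larvae, pupae minus larvae, it was -3.11 for larval cuticle genes, 1.66 for heat shock genes and 0.658 for cytoplasmic ribosomal protein genes (adjusted p = 1.5e-13, 1.3e-09 and 2.6e-05, and 0.090, 0.063 and 0.91 with an estimated correlation). The pupal call of the ribosomal protein list was lost with the kind of library as a covariate.

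All 27 neuron and synapse genes had negative changes in knock-out embryos. The tables argue against the kind of library as the whole cause: in rRNA-poor libraries alone, where the third run of wild-type embryo 2 is the only wild-type library, all 27 genes had negative changes with a median of -1.25 (quartiles -1.41 and -1.06), and with the kind as a covariate the median was -1.05. Unfertilised eggs as the whole cause would lower zygotic genes as well, but the segmentation genes had a median of 0.61 (quartiles 0.43 and 0.70) with 24 of 24 positive, and of 0.29 with 23 positive in rRNA-poor libraries alone. Younger knock-out embryos may account for part of the pattern. Of 9957 genes, the 996 with the highest larval and pupal levels relative to embryos had an embryonic median of -0.68. The 996 with the lowest had 0.43, a difference of -1.11, and of -1.01 in rRNA-poor libraries alone. The median log2 ratio of larval and pupal to embryonic levels was -0.17 for the neuron and synapse list and -3.29 for segmentation genes. As a list, the neuron and synapse genes were thus not higher at the later stages. Their embryonic median of -1.24 also lay below the -0.68 of the late-biased genes. The ratio of larval and pupal to embryonic levels does not order genes by age within the embryo. These values therefore cannot decide whether an age difference accounts for the size of the neuron and synapse median. Embryos arrested early, a slower development of the knock-out and a difference in the time of collection would look alike here, and none of these was tested.

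Of 37 immunity genes 13 rose in knock-out pupae, where the kind of library followed the genotype. Within wild-type larvae 1 the rRNA-poor library exceeded the rRNA-rich one by a median log2 difference of 0.32 over the list (quartiles 0.09 and 0.62), and by 0.33 in wild-type embryo 2, where the rRNA-poor run may be another collection, against 1.95 between the pupal genotypes and 1.99 with the kind as a covariate, which argues against the kind of library as the whole cause. Among the 13 genes that rose, the difference within wild-type larvae 1 had a median of 0.42 and a largest value of 2.35. By chi-square over its degrees of freedom, the 2 runs of wild-type larvae 1 differed by 683 and wild-type larvae 1 and 2 by 688. Whether these runs differ in more than the kind of library is not known. A single knock-out sample is also argued against, with median log2 ratios to the wild-type mean of 1.90 and 2.12 in knock-out pupae 1 and 2. An infection or another state of the knock-out culture, a different mix of pupal ages and an effect of the genotype stay open, and none of these was tested.

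CG7804 was still read in knock-out larvae and pupae. Reads of its parent gene TBPH placed on CG7804 are argued against by embryos, which had 0.223 CG7804 reads for each 1000 TBPH reads (5 against 22460), while the knock-out larval and pupal samples had 16.1, 138, 93.8 and 73.9. Wild-type RNA as the whole cause would leave every gene with at least the share of its wild-type level that CG7804 kept. With either wild-type sample as the reference, the 10 genes named lower in pupae kept at most 15.6% in the knock-out samples by their reads. CG7804 kept 23.6% to 126.7% in them. Those named lower in larvae kept at most 6.26% in knock-out larvae 2, against 38.1% to 42.0% for CG7804. With 3 reads in place of 0, the pupal genes reached up to 18.7% (CG34251). In knock-out larvae 2, 3 reads would be 50.9% to 64.3% for Nepl8, which cannot decide, and 1.91% to 2.92% for mthl8. These values argue against wild-type RNA as the whole cause in knock-out pupae and knock-out larvae 2. In knock-out larvae 1, where CG7804 had 4 reads and kept 4.28% to 4.72%, the genes named lower kept 0% (5 genes) to 13.4%, but 0 reads there allow up to 4.39% to 6.72% for mthl8 and 3.69% to 8.08% for lncRNA:CR43166 (3 reads), so that wild-type RNA, an altered transcript of the knock-out allele and a mixture of genotypes within the stock stay open; the last 2 were not tested in any sample.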

How the results depend on the processing

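All tests with library kind, with 1 kind of library alone, without rRNA genes and with crossed sample numbers were chosen after the kinds were seen. Of the values of 173 gene results over all alternatives, 4033 kept their side of the threshold, and 861 kept the direction but lost the call. No called gene result reversed. The direction of TBPH, which was not called, was not counted, and in pupae it turned from 0.11 to -0.14 with library kind as a covariate. Among gene lists, the pupal medians of oxidative phosphorylation and ribosomal protein genes turned from 0.57 and 0.42 to -0.17 and -0.19 with library kind as a covariate, where neither was called. The split of the embryo calls turned without wild-type embryo 2, which left only rRNA-rich wild-type embryo libraries against rRNA-poor knock-out ones. Counts moved by over 1.5 times as follows, and except where fewer samples or a stricter threshold were used the cause was not tested. DESeq2-type size factors gave 2132 genes in embryos, 684 in larvae, 806 on average and 1109 that differed between stages. Upper-quartile scaling gave 2012 in embryos (16.6% higher), 908 on average and 1300 that differed. The DESeq2 test gave 3322 (48.2% higher), 1164, 712, 1657 and 2669 in embryos, larvae, pupae, on average and for the difference. Limma voom gave 1944 in embryos (37.6% higher) and 703 in larvae. Each run as a replicate gave 4194 (57.2% higher), 2147, 645, 2267 and 3728, and voom over all runs 736 in larvae and 345 on average. Fits of 1 stage gave 558 in embryos, 0 in larvae (edgeR, 2048 at an unadjusted p under 0.05) and 474 in pupae, and 1 flow cell gave 223 in larvae and 12 in pupae. Wild-type embryo 2 without its run 3 gave 3391 in embryos (67.1% higher), 1471 on average and 1789 that differed. Library kind as a covariate gave 1552, 1232, 288 on average and 1752 that differed. rRNA-poor libraries alone gave 2949 in embryos and 1407 in larvae, and rRNA-rich ones 91 in larvae. The rRNA-poor fits held only wild-type larvae 1 and knock-out larvae 2 at the larval stage, and only run 3 of wild-type embryo 2 for wild-type embryos. The rRNA-rich larval fit held only knock-out larvae 1 for the knock-out. A lone sample has no spread of its own, so counts and list calls of these fits borrow the spread of other groups. No conclusion is drawn from these counts. A 2-fold minimum gave 266 on average, and an adjusted p under 0.01 gave 104 that differed.

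The sample numbers do not pair the samples (correlations of deviations 0.14, -0.18 and 0.05 in embryos, larvae and pupae), and a replicate block gave 799, 370, 169 and 471 genes in embryos, larvae, pupae and on average, and 323 on average with crossed larval numbers. Leaving out each sample in turn, where a lone sample is assumed to vary like the other groups, gave 26 (without knock-out embryo 1) to 1696 (without wild-type embryo 2) in embryos, and 53 (without wild-type larvae 1) to 470 (without wild-type embryo 1) in larvae. It gave 17 (without knock-out pupae 1) to 221 (without knock-out larvae 1) in pupae, 72 (without knock-out pupae 1) to 767 (without knock-out larvae 1) on average, and 120 (without wild-type larvae 1) to 705 (without wild-type embryo 2) that differed. CG7804 ranged from -3.49 to 1.72 in embryos, -4.48 to -1.32 in larvae and -1.81 to 0.15 in pupae. Its larval change was called with each run as a replicate (-1.85) and with library kind as a covariate (-2.34). Both fits counted runs or libraries of 1 sample as separate replicates. In rRNA-poor libraries, which hold only wild-type larvae 1 and knock-out larvae 2 at that stage, it was -1.30. With an estimated correlation 0 lists were called at each stage, and fry called 5, 1 and 1. Without each sample in turn, camera called 13 to 19, 12 to 18 and 6 to 9. Of 20 named genes per stage, 15 in embryos, 0 in larvae and 8 in pupae were called under all other settings run for them (17, 17 and 15), and 12, 16 and 8 without each sample in turn; of 12 named on average, 7 were called under all 15 other settings and 3 without each sample in turn; the fit of larvae alone lost the larval calls. Depth limits low genes: 1 knock-out larval sample held 5396686 reads, where 3 reads are 0.678 CPM.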

Other observations

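The split tests and the tests of a region near CG7804 and of neighbouring genes were written before their results were seen; the count of neighbours that do not overlap was chosen after.

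In embryos, 2 of 20 phototransduction genes fell (4 adjusted over the list alone; median -0.80, adjusted p = 0.024, and adjusted p = 0.65 with an estimated correlation), and of 11 juvenile hormone genes the receptor gene gce and its target Kr-h1 fell (4 adjusted over the list alone; median -0.54, adjusted p = 0.045, and adjusted p = 0.52 with an estimated correlation). Larval serum and fat body proteins had a median of -1.73 in embryos over 6 genes (adjusted p = 0.025, and adjusted p = 0.65 with an estimated correlation), of which edgeR called 0 (3 fell adjusted over the list alone), with 3 at an unadjusted p under 0.05, DESeq2 4 and voom 0. The phototransduction call was lost without wild-type embryo 2 (adjusted p = 0.11), the juvenile hormone call without wild-type embryo 1, without knock-out embryo 1 and with DESeq2-type size factors (adjusted p = 0.078, 0.079 and 0.052; median -0.35 with the kind of library as a covariate), and the serum and fat body call without wild-type embryo 1 and in rRNA-poor libraries alone (adjusted p = 0.13 and 0.073). In larvae, hemocyte genes had a median of 0.46, neurogenesis genes -0.48 and cytoplasmic ribosomal protein genes -0.23 (adjusted p = 0.023, 0.040 and 0.044, and adjusted p = 0.51, 0.78 and 0.99 with an estimated correlation). Of these, edgeR called 0 over all genes, with 5, 4 and 1 at an unadjusted p under 0.05 (5 hemocyte genes and 1 neurogenesis gene rose adjusted over the list alone), DESeq2 called 5, 1 and 0, and voom 3, 1 and 0. The hemocyte call was lost without wild-type larvae 2 and in rRNA-poor libraries alone (adjusted p = 0.11 and 0.14), and the median was 0.26 with the kind of library as a covariate. The neurogenesis call was lost without knock-out embryo 1, knock-out embryo 2, wild-type larvae 1 or knock-out larvae 2, under a replicate block and in rRNA-rich libraries alone (adjusted p = 0.050, 0.050, 0.087, 0.41, 0.056 and 0.25). The ribosomal protein call was lost without knock-out embryo 1 or 2, wild-type larvae 1, knock-out larvae 1, or wild-type pupae 1 or 2, and under a replicate block (adjusted p = 0.051, 0.052, 0.94, 0.90, 0.069, 0.069 and 0.070). Genes tied to TBPH were not called as a list at any stage (adjusted p = 0.69, 0.46 and 0.22), nor were the strain marker genes (adjusted p = 0.072, 0.73 and 0.66) or the Hox genes (adjusted p = 0.69, 0.73 and 0.48).

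On average over the stages, neuron and synapse genes had a median of -0.54 with 10 of 27 called lower (15 adjusted over the list alone), DNA replication genes 0.31 and ecdysone response genes -0.40 (adjusted p = 3.3e-10, 1.9e-06 and 0.00037, each with adjusted p = 0.99 with an estimated correlation). Oxidative phosphorylation, immunity and ribosomal protein genes had medians of 0.35, 0.32 and 0.16 (adjusted p = 3.6e-05, 0.0022 and 0.012, each with adjusted p = 0.99 with an estimated correlation). With the kind of library as a covariate, 2 of the 27 neuron and synapse genes were called lower (median -0.30), and the medians of the DNA replication and immunity lists were 0.20 and 0.34. The ecdysone response, oxidative phosphorylation and ribosomal protein lists then had medians of -0.29, -0.0012 and -0.096 and were no longer called (adjusted p = 0.14, 0.67 and 0.96).

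Other splits exchanged the genotypes within stages, with 60 splits drawn from 108. As many genes on average came from 1 of the 60, the real one, with 536 genes against 92 in the highest other split. A random grouping of these samples thus seldom gave such a count. In pupae the kind of library followed the genotype, so the splits cannot tell the genotype from the kind of library. Nor can they tell it from differences between the collections of the genotypes.

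A region linked to CG7804 was tested as a hypothesis for the genes changed on average. Within 1 Mb of CG7804, 7 of 276 genes were called against 525 of 12906 elsewhere. The odds ratio was 0.614 (95% interval 0.243 to 1.29, Fisher's exact adjusted p = 0.60), which argues against an excess of calls on average there. CG17177 and CG33258, named above, were among the 7. For the calls of larvae and pupae the upper 95% bounds were 2.43 and 2.49, which leave a 2-fold excess open. Differences between the stocks along the whole genome were tested by neighbours: 74 of 532 called genes lay next to another called gene of the same direction, against a median of 26 and a highest value of 58 in 10000 shuffles (permutation p = 0.0001, the smallest these shuffles can give). Without overlapping neighbours there were 63, against a median of 21 and a highest value of 51. Such runs, as Cyp6a9, Cyp6a20 and Cyp6a8, or CG10562, CHKov1 and CHKov2, may reflect differences between the stocks, and clusters of genes regulated together would give the same count of 74.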
